A study of Mus musculus with 27 samples.

How the data were processed

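The counts per gene are those of the authors, taken as deposited. Per the submitters' processing notes, reads were aligned with STAR 2.5.0a to mm10 and counted with featureCounts 1.4.3-p1, and edgeR, without a stated version, was named for the analysis. The annotation, the strand setting and the role of edgeR in the table are not given in the sources used here. The table has 22340 rows and 27 libraries. Library totals, detection and correlations were computed from these counts. The lowest Spearman correlation between 2 libraries was 0.966.

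Gene coordinates, GC content and 3' untranslated regions came from GENCODE release M21. Of the 22340 symbols 22164 were matched, 696 of them through an older symbol, and 18433 had a 3' untranslated region. The symbol March6 stands on 2 rows and both rows were kept.

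Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 18087 and took out 4253 rows holding 0.0116% of the counts. Counts were normalized by TMM, and all 27 libraries were fitted in 1 quasi-likelihood model of edgeR 4.0.16 with 1 mean per group and robust dispersion estimation. The common biological coefficient of variation was 0.175, with 18 residual degrees of freedom and a median of 10.4 prior degrees of freedom. Each result used a quasi-likelihood F-test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The results were ipsilateral against contralateral, ipsilateral against sham and contralateral against sham at each of 4 times, the mean of the 4 ipsilateral to contralateral effects, a test that this effect differs between the 4 times, and the effect at 24 h minus that at 3 h. Log2 fold changes are model estimates with SE derived from the test statistic, and CPM are given with SD. For genes with few or no counts in 1 group, ratios use pooled counts with a 95% interval, or a floor of 3 counts over the group, and these intervals and floors cover counting error only. Logarithms for the principal components used a prior count of 2.

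The comparisons, the tests, the 33 gene lists, the rule for naming genes and the first alternatives were fixed before the data were examined. The naming rule took, for ipsilateral against contralateral, the 10 largest rises and 6 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, and all 3 ipsilateral libraries on the same side of all 3 contralateral ones. For contralateral against sham it took 5 and 5. For the test of differing effects it took the 5 smallest p per time of largest effect. For each list it took up to 4 members with the smallest p. Slc1a2, Slc1a3, Glul, Fos, Gfap, Hspa1a and Hspa1b were followed in every comparison. Some genes picked by the rule are left out of the text for brevity.

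Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. Members were also counted after adjustment over the list alone. Camera with an estimated correlation and the rotation test fry were run as alternatives. The listed genes Camp, Trac, Lhfpl3, Hmgcs1, C1s and Hbb-b1 have no row under a known symbol and were not analysed here. The series title names AGO CLIP but the table holds no CLIP data. Seed sites of 15 microRNA families were therefore counted as 8mers in the 3' untranslated region of 15593 tested genes. Each set was tested with camera and against 1000 random sets drawn from 20 length bins, with random seed 1.

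Replicate numbers mark surgery days, so it was asked whether they pair libraries. After removal of group means, libraries with the same number in distinct groups had a mean correlation of 0.117 over 108 pairs, 59 of them above 0.1, and libraries with distinct numbers -0.058 over 216 pairs, 46 of them above 0.1. Contralateral and ipsilateral libraries with the same number had a mean correlation of 0.317 at 3 h, 0.109 at 6 h, 0.0207 at 12 h and 0.234 at 24 h. The model without a block was kept as planned, and a block of replicate number was run as an alternative.

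The alternatives set in advance were size factors of DESeq2 (RLE) in place of TMM, no filter, a filter of at least 1 CPM in at least 3 libraries, abundant RNAs left out (Rn45s, Rn7sk, Rmrp, Rpph1, Malat1, Meg3 and mitochondrial transcripts), only the libraries of the compared groups, DESeq2 1.42.0, a replicate block, a replicate block within each time, each library left out in turn, and each replicate number left out of every group. DESeq2 used its Wald test, except for the test of differing effects, where it used a likelihood ratio test on the 24 libraries from animals with a stroke. Seed sets were repeated with 7mer sites. Added after the results were seen were a correction for GC content, the same with a replicate block, and the omission of 2 libraries that stand apart on technical measures, contralateral replicate 1 at 3 h and ipsilateral replicate 1 at 24 h. A first version of this omission also left out ipsilateral replicate 2 at 12 h, chosen by its place on the first principal component, and was dropped because that choice depends on the outcome. The GC correction subtracts, per library, a smooth trend of the deviation from the mean log2 CPM over GC content, which also removes any GC trend that goes with a group. A count was called moved when it changed by more than 1.5 times.

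Recovery was measured on simulated counts with a known change in 200 genes per comparison. The changed genes were drawn from those of at least 1 CPM. Apart from the change, groups shared the same mean and dispersion per gene, without day effects or GC trends. Real contralateral libraries at 3 h and ipsilateral libraries at 24 h differed more among themselves than sham libraries did. Recovery in the comparisons that use them may therefore be lower, and the number of false calls may differ. Of 67, 67 and 66 genes changed 1.5-, 2- and 4-fold, the edgeR test found 32.8, 71.6 and 97.0% in the ipsilateral to contralateral comparison at 3 h, 37.3, 82.1 and 98.5% at 24 h, and 31.3, 83.6 and 98.5% for contralateral against sham at 12 h. For the test of differing effects it found 2.99, 62.7 and 90.9%. Among the unchanged genes 7, 5, 8 and 4 were called.

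R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.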

Results

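Gene expression was measured by sequencing of total RNA, depleted of ribosomal RNA, from the cortex of C57BL6 mice after a transient stroke or after sham surgery. In the stroke model a suture blocked the right middle cerebral artery and was then withdrawn, and cortex from the ipsilateral (occluded) and the contralateral hemisphere was taken 3, 6, 12 or 24 h after blood flow returned. The 27 libraries formed 9 groups of 3: sham, and ipsilateral and contralateral cortex at each of the 4 times. Total counts per library ran from 26505996 to 48830897. Group means ran from 37.1 M in contralateral cortex at 3 h to 44.4 M in contralateral cortex at 24 h. Levels are given as CPM, counts scaled to the library total of the filtered genes after TMM normalization. Of the 22340 genes in the table, 588 had no count in any library and 18087 were abundant enough to be tested. Between 18579 and 19935 genes had at least 1 count in a library. Replicates came from distinct surgery days, so the p-values of single genes measure the spread between libraries of distinct days. Camera with a preset correlation and the random gene sets measure the spread over genes instead. The labels do not say whether both hemispheres of 1 animal were used, which hemisphere the sham tissue came from, or how long after surgery it was taken. Library numbers ran on within each replicate number, so surgery day cannot be told apart from a possible batch of libraries. Contralateral and ipsilateral libraries of the same time and replicate had neighbouring numbers, which does not settle whether they came from the same animal.

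The libraries were ordered mainly by the side of the occlusion. On the first principal component, which held 24.3% of the variance, sham and contralateral libraries lay between -32.9 and -14.7. Ipsilateral libraries lay at 3 h between 4.59 and 7.69, at 6 h between 27 and 39.4, at 12 h between 5.11 and 53.6 and at 24 h between 45.6 and 58.2. Transcripts of the 2 mitochondrial ribosomal RNA genes took 24.4 to 40.4% of the counts, with the highest share in replicate 1 of ipsilateral cortex at 24 h. Replicate 1 of contralateral cortex at 3 h followed the GC content of the genes over a range of 1.01 on the log2 scale, against at most 0.338 in every other library.

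The comparison of ipsilateral with contralateral cortex at each time asks which transcripts respond to occlusion and reperfusion. At 3 h the largest rises were in inducible chaperones and immediate early genes. Hspa1a, which encodes the stress-inducible chaperone HSP70 (mm10, chromosome 17, 34969190 to 34972156, minus strand), averaged 173 ± 49.6 CPM (SD, n = 3) ipsilaterally and 3.36 ± 0.6 contralaterally, a 51.7-fold rise (log2 fold change 5.69 ± 0.39, SE; adjusted p = 1.25e-07). Its near-identical neighbour Hspa1b (chromosome 17, 34956436 to 34959238, minus strand) rose by 5.61 ± 0.44 on the log2 scale, and the split of reads between this pair is uncertain. Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039, minus strand), rose 18.8-fold (4.23 ± 0.51, adjusted p = 0.000244). The small heat shock protein gene Hspb1 rose 6.56-fold, the HSP70 cochaperone gene Dnajb1 3.78-fold, and Ttll13, of the tubulin-modifying ligase family, 5.29-fold. Of the 18087 genes tested, 42 rose and 3 fell, and 36 of the 42 rose at least 2-fold.

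By group at 3 h, 6 of the 17 heat shock proteins and chaperones rose (9 adjusted over the list alone). The list ranked above other genes (camera adjusted p = 1.02e-34, and adjusted p = 0.00108 with an estimated correlation). Of the 23 immediate early genes, which neurons and glia switch on within minutes of stimulation, 9 rose (16 adjusted over the list alone). The number was between 1 without contralateral replicate 1 and 8 without ipsilateral replicate 1 (adjusted p = 0.00881 with an estimated correlation). They included Atf3, the neuronal activity factor Npas4 (9.02-fold), Jun (3.17-fold), Egr4 (2.96-fold) and Fos (6.89-fold, adjusted p = 0.0456). Against sham Fos was 2.32-fold higher ipsilaterally and 2.97-fold lower contralaterally, and neither passed (edgeR adjusted p = 0.502 and 0.471). Of the 28 cytokine, chemokine and NF-kappaB feedback genes only Tnf and Osm rose (13 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation). Without contralateral replicate 1 only 1 rose. Tnf, the cytokine tumour necrosis factor, had 100 ipsilateral counts against 3, a ratio of 30.5 with a 95% counting interval of 10.2 to 151. The 3 genes that fell were Ccbe1 (1.84-fold lower), the potassium channel gene Kcnd1 (1.62-fold lower) and Lrrc57 (1.5-fold lower). Markers of tissue next to the cortex had positive medians with no member passing the test (2 and 0 adjusted over the list alone). The 9 choroid plexus markers had a median log2 fold change of 2.96 (camera adjusted p = 0.000721, adjusted p = 0.484 with an estimated correlation). The 11 striatal neuron markers had 0.71 (camera adjusted p = 0.00558, adjusted p = 0.692 with an estimated correlation).

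The count of 45 genes at 3 h depended on single libraries. It was 20, 132 and 23 without contralateral replicates 1, 2 and 3, and 23 and 23 without ipsilateral replicates 2 and 3. Of the 13 genes named by the fixed rule at 3 h, 6 kept their call without any single library. Npas4 reached an adjusted p of 0.0923 and 0.0632 without contralateral replicates 1 and 3, and 0.117 with a replicate block within each time. Jun reached 0.0748 and Egr4 0.0966 without contralateral replicate 1. Osm reached 0.139 and 0.121 without contralateral replicates 1 and 3, and 0.0993 and 0.161 without ipsilateral replicates 2 and 3. Fos reached 0.155, 0.0614 and 0.121 without contralateral replicates 1, 2 and 3, 0.0516, 0.182 and 0.123 without ipsilateral replicates 1, 2 and 3, and 0.118 with the block within each time. Ccbe1 reached 0.0904, 0.0549 and 0.121 without the contralateral replicates in turn, and 0.306 and 0.172 without ipsilateral replicates 2 and 3. Kcnd1 reached 0.154 and 0.0632 without contralateral replicates 1 and 3, and 0.166 and 0.158 without ipsilateral replicates 2 and 3. Lrrc57 reached 0.129, 0.0549 and 0.0632 without the contralateral and 0.113, 0.182 and 0.154 without the ipsilateral replicates in turn, and 0.0667 with the block within each time.

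At 6 h the largest rises were again in chaperones and immediate early genes. Hspa1a reached 404 ± 55.6 CPM (SD, n = 3) against 3.88 ± 0.233, a rise of 6.7 ± 0.41 on the log2 scale (adjusted p = 1.09e-08). Atf3 rose 41.9-fold, Npas4 17.7-fold, Egr2, a zinc finger immediate early factor, 16.8-fold, and Fos 16-fold (4 ± 0.59, adjusted p = 0.000326). Against sham Fos was 3.63-fold higher ipsilaterally (edgeR adjusted p = 0.0467) and 4.4-fold lower contralaterally (edgeR adjusted p = 0.515). Rrad, a Ras-like regulator of calcium channels, rose 10.4-fold. Across all genes 1058 rose and 387 fell, and 405 rose and 25 fell at least 2-fold. The largest falls were in Alox12b, a lipoxygenase (2.26-fold lower, adjusted p = 0.00705), Ackr2, a scavenging chemokine receptor (2.14-fold lower), Ccbe1 (2.1-fold lower), Kirrel2 (2.06-fold lower) and Tmem119, a microglia marker (2.03-fold lower).

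Of the 23 immediate early genes 17 rose at 6 h (21 adjusted over the list alone; adjusted p = 0.00788 with an estimated correlation), among them Jun (5.98-fold), Egr1 (5.27-fold) and Ier2 (4.59-fold). Chaperones rose in 13 of 17 (17 adjusted over the list alone, adjusted p = 0.000194 with an estimated correlation). Of the 19 p53 target and cell death genes 6 rose (10 adjusted over the list alone; adjusted p = 0.0369 with an estimated correlation), led by the growth arrest gene Gadd45b (4.9-fold) and including Bcl2l11, a BH3-only death gene (2.09-fold). Of the 28 cytokine genes 11 rose (16 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), among them the neutrophil attractant Cxcl1 (12.9-fold) and the feedback inhibitor Tnfaip3 (2.56-fold). This count ran from 6 without contralateral replicate 2 to 8 without ipsilateral replicate 1. Of the 21 reactive astrocyte genes 6 rose (8 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), including the bile acid transporter family gene Slc10a6 (8.53-fold). Only 2 rose without contralateral replicate 3, and 6 without ipsilateral replicate 3. Of the 16 circadian clock genes 7 rose (8 rose and 2 fell adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), among them Per2 (1.96-fold) and Bhlhe41 (1.81-fold). Here 3 rose without ipsilateral replicate 2 and 8 without ipsilateral replicate 3. Of 15 activity-regulated secreted and synaptic genes 4 rose (5 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), including Bdnf, a neurotrophin (2.11-fold), and Nptx2 (2.89-fold). The 18 neuron markers had 4 members that fell (4 adjusted over the list alone; median -0.2; adjusted p = 0.251 with an estimated correlation). None passed without ipsilateral replicate 2.

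Without 1 library the 6 h count of 1445 genes became 912, 823 and 756 without contralateral replicates 1, 2 and 3, and 811 and 516 without ipsilateral replicates 1 and 2. Of the 16 genes named by the rule 15 kept their call without any single library, and Tmem119 reached an adjusted p of 0.0553 without ipsilateral replicate 2.

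At 12 h chaperones, the chemokine gene Ccl4 and the oxidative stress gene Hmox1 were among the largest rises. Hmox1, the inducible heme oxygenase (chromosome 8, 75093621 to 75100589, plus strand), averaged 35.1 ± 15.2 CPM (SD, n = 3) against 1.96 ± 0.543, an 18-fold rise (4.17 ± 0.34, adjusted p = 6e-08). The chemokine gene Ccl4 rose 82.2-fold (6.36 ± 1.24, adjusted p = 0.00241), Hspa1a 55.3-fold, Atf3 27.8-fold and Ttll13 16.8-fold. The chemokine gene Ccl9 rose 14.9-fold and the secreted stress hormone gene Stc2 9.97-fold. Lower on the ipsilateral side were Sult1a1, a sulfotransferase (2.15-fold lower), Rxfp1, a relaxin receptor (2.14-fold lower), Cd34 (2.14-fold lower) and P2ry12, a purinergic receptor of resting microglia (2.11-fold lower, adjusted p = 0.0159). In total 1437 genes rose and 777 fell, of which 532 and 27 changed at least 2-fold.

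Among the groups at 12 h, 14 of 17 chaperones rose (14 adjusted over the list alone; adjusted p = 0.000245 with an estimated correlation). So did 9 of 19 p53 target and cell death genes (12 adjusted over the list alone; adjusted p = 0.00419 with an estimated correlation), including the stress gene Sesn2 (4.63-fold) and the death gene Pmaip1 (3.61-fold). Of the 16 oxidative stress and metallothionein genes 5 rose (9 adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation), among them Hmox1, the thioredoxin reductase gene Txnrd1 (2.29-fold) and the stress cytokine Gdf15 (17.5-fold). Of the 28 cytokine genes 18 rose (23 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation), including Ccl12 (13.8-fold) and Tnf (11.9-fold). Of the 21 reactive astrocyte genes 11 rose (15 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation), including Slc10a6 (51.8-fold), the oncostatin M receptor gene Osmr (4.44-fold) and the intermediate filament gene Vim (2.38-fold). These counts ran from 8 and 3 without ipsilateral replicate 3 to 21 and 11 without ipsilateral replicate 2. Gfap, the astrocyte filament gene, rose 1.96-fold (adjusted p = 0.0227). Its adjusted p was 0.0873 and 0.0792 without contralateral replicates 1 and 2 and 0.0696 and 0.0564 without ipsilateral replicates 2 and 3, and 0.0643 with a replicate block within each time. Of the 18 endoplasmic reticulum stress genes 4 rose (7 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), including the pseudokinase gene Trib3 (23.2-fold) and Ddit3, which encodes CHOP (2.3-fold). Of the 28 voltage-gated potassium and sodium channel genes 11 fell and 1 rose (14 and 2 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation), such as the sodium channel genes Scn1a (1.55-fold lower) and Scn2a1 (1.59-fold lower). Only 7 fell without contralateral replicate 1.

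The 12 h count of 2214 genes became 1362, 1448 and 1459 without contralateral replicates 1, 2 and 3, and 889 and 1435 without ipsilateral replicates 1 and 3. Of the 16 genes named by the rule 14 kept their call. Ccl9 reached an adjusted p of 0.125 without ipsilateral replicate 3. P2ry12 reached 0.0567 without contralateral replicate 1 and 0.0639 and 0.0803 without ipsilateral replicates 1 and 3.

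At 24 h the largest rises included the protease genes Mmp3 and Mmp12 and the chemokine genes Ccl4 and Ccl2. Mmp3, the secreted protease stromelysin (chromosome 9, 7445822 to 7455975, plus strand), had 1756 counts ipsilaterally and none contralaterally, which makes it at least 637-fold higher against a floor of 3 counts over the group (adjusted p = 0.00209). Ccl4 had a ratio of 358 with a counting interval of 98.8 to 2970, from 2 contralateral counts. The macrophage elastase gene Mmp12 rose 161-fold (7.33 ± 1.19, adjusted p = 0.000349), and the monocyte attractant Ccl2 118-fold to 12.8 ± 10.4 CPM (SD, n = 3) from 0.106 ± 0.0292. Tgm1, a transglutaminase, rose 111-fold, Ptx3, a pentraxin, 82.8-fold and the interleukin 1 antagonist gene Il1rn 141-fold. Hspa1a was still 36.7-fold higher (5.2 ± 0.38, adjusted p = 1.81e-07). The largest falls were in Cbln4, a synaptic organizer (2.56-fold lower), the immunoglobulin gene Ighm (2.28-fold lower) and Lamp5, an interneuron marker (2.26-fold lower, 41.6 ± 6.39 against 94.0 ± 10.9 CPM, adjusted p = 2.5e-06). They were followed by Selplg, a microglia marker (2.21-fold lower), Abca9, a lipid transporter family gene (2.17-fold lower), and Bhlhe22, a cortical neuron transcription factor (2.1-fold lower). In all 1762 genes rose and 1693 fell, but 876 of the rises and 29 of the falls were at least 2-fold.

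By group at 24 h, 27 of 28 cytokine genes rose (27 adjusted over the list alone; adjusted p = 0.013 with an estimated correlation). So did 20 of 23 interferon-stimulated genes, with 1 falling (21 and 1 adjusted over the list alone; adjusted p = 0.00892 with an estimated correlation) and 19 of 21 reactive astrocyte genes (21 adjusted over the list alone; adjusted p = 0.0124 with an estimated correlation). Examples were Tnf (36-fold), the antiviral gene Rsad2 (7.96-fold), Osmr (7.55-fold), Vim (4.88-fold) and Gfap (4.89-fold; 408 ± 185 against 83.3 ± 5.3 CPM). Of the chaperones 14 of 17 rose (16 adjusted over the list alone; adjusted p = 0.00406 with an estimated correlation). Of the oxidative stress genes 9 of 16 rose (9 adjusted over the list alone; adjusted p = 0.00406 with an estimated correlation). Of the p53 target and cell death genes 10 of 19 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.0103 with an estimated correlation). Of the 18 neuron markers 11 fell and none rose (11 adjusted over the list alone; median -0.58; adjusted p = 0.0103 with an estimated correlation). Among them were the synaptic vesicle gene Syp (1.64-fold lower, adjusted p = 3.36e-05), the cytoskeletal gene Stmn2 (1.7-fold lower) and the vesicular glutamate transporter gene Slc17a7 (1.65-fold lower). Of the 28 channel genes 14 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 0.0471 with an estimated correlation), including Scn1a (1.63-fold lower) and Kcnq3 (1.46-fold lower). Only 7 fell without contralateral replicate 1. Replicate 1 of this ipsilateral group had the highest mitochondrial ribosomal RNA share of all libraries.

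At 24 h, of 20 microglia markers 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.487), with Fcrls up 3.08-fold and the resting-state markers Selplg and Tmem119 down 2.21- and 1.99-fold. Only 1 rose without ipsilateral replicate 1 and 8 without ipsilateral replicate 3. Of 16 neutrophil and monocyte markers 7 rose (10 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), including the scavenger receptor gene Msr1 (26.2-fold). Only 1 rose without ipsilateral replicate 1, and 10 without ipsilateral replicate 3. Of 16 endothelial markers 5 rose, such as Ly6a (2.19-fold), and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.191). Only 1 rose without ipsilateral replicate 1, and none fell without contralateral replicate 1. Of 16 homeostatic astrocyte markers 3 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation, and camera adjusted p = 0.0485, or 0.0508 with a replicate block), and 6 fell without ipsilateral replicate 1. Of 8 oligodendrocyte precursor markers 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0422, or 0.0508 with a replicate block; adjusted p = 0.472 with an estimated correlation), including Gpr17 (2.05-fold lower), and 1 fell without ipsilateral replicate 3. Of 12 oligodendrocyte markers 2 rose (2 adjusted over the list alone; camera adjusted p = 0.584), with none rising without ipsilateral replicate 1. Of 11 mural cell markers 1 rose (0 adjusted over the list alone; camera adjusted p = 0.871). Of 3 lymphocyte markers 1 rose, the kinase gene Lck (2.83-fold, adjusted p = 0.01; 1 adjusted over the list alone; camera adjusted p = 0.296). None of the 10 fibroblast and meningeal markers passed the edgeR test (3 higher and 4 lower adjusted over the list alone; 2 rose with a replicate block; camera adjusted p = 0.871; median -0.2, mean 0.1). Of 8 blood cell markers 3 rose (4 adjusted over the list alone; adjusted p = 0.342 with an estimated correlation), including the platelet chemokine Pf4 (9.32-fold), with 1 rising without contralateral replicate 1. Of 8 complement genes 4 rose (4 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation), including the anaphylatoxin receptor genes C3ar1 (5.39-fold) and C5ar1 (5.84-fold). Of 18 hypoxia-inducible genes 5 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.324), with 3 rising without contralateral replicate 1. Of 17 glucocorticoid-responsive genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0818), and 3 rose without contralateral replicate 2. Of 18 proliferation genes 2 rose (1 adjusted over the list alone; camera adjusted p = 0.0631), with none rising without contralateral replicate 2. Of the 23 immediate early genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0818), with none falling with a replicate block and 2 rising without ipsilateral replicate 1.

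With an estimated correlation the lists with a camera adjusted p under 0.05 between hemispheres were fewer. Chaperones passed at all 4 times, immediate early genes at 3 and 6 h, activity-regulated genes at 3 h, p53 targets at 6, 12 and 24 h, and oxidative stress genes at 12 and 24 h. At 24 h cytokines, interferon-stimulated genes, reactive astrocyte genes, neuron markers and channel genes passed too.

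The 24 h count of 3455 genes became 2231 without contralateral replicate 1 and stayed within 1.5 times of its value without any other single library. All 16 genes named by the rule kept their call without any single library.

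**Figure D1:**
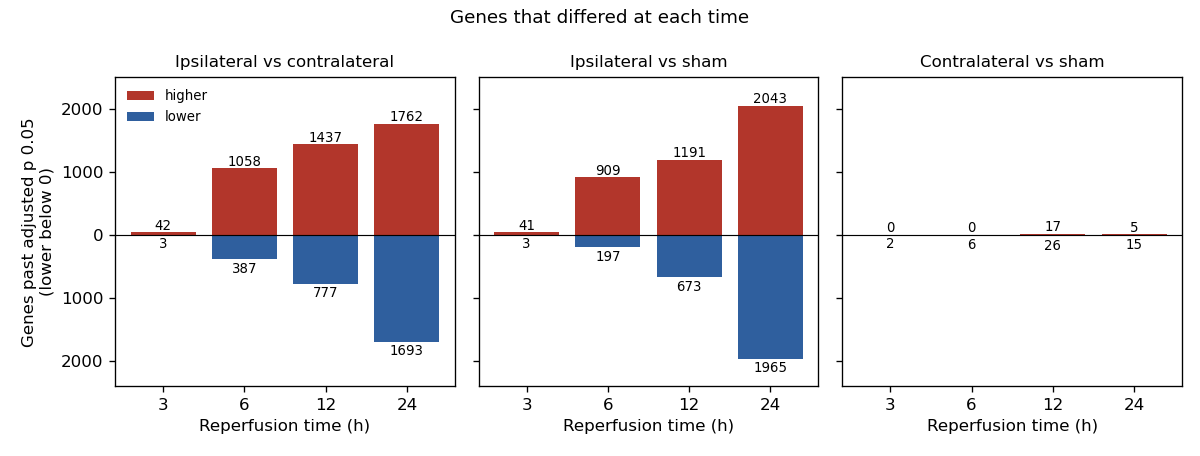
Number of genes that rose and fell in each comparison (edgeR, adjusted p under 0.05, 3 libraries per group), by reperfusion time in hours. In the fit of all libraries the count of rises between hemispheres grew from 42 at 3 h to 1762 at 24 h. Contralateral cortex differed from sham in at most 43 genes. With only the 2 groups compared, 18, 2445, 2665 and 2433 genes passed between hemispheres in either direction at 3, 6, 12 and 24 h.

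Genes called at 1 time between hemispheres were often called at the next, from separate libraries. Of the 42 genes higher at 3 h, 37 were also higher at 6 h, where 2.46 would be shared if the times were independent. At 6 and 12 h 599 higher and 171 lower genes were shared, against 84.1 and 16.6, and at 12 and 24 h 742 and 544, against 140 and 72.7. Genes are not independent replicates. All times also shared 1 fit and its estimate of the spread of each gene. The numbers given for independent times may therefore be too low as a reference. The mean of the 4 effects passed the test in 5967 genes, 3208 higher and 2759 lower, of which 673 and 8 changed at least 2-fold. The rises included 21 of 23 immediate early genes, 16 of 17 chaperones, 26 of 28 cytokine genes and 20 of 21 reactive astrocyte genes, and the falls 13 of 22 glutamate receptor genes. No list test is given for these counts, and 5967 of all 18087 tested genes passed here. Measured from sham, part of the immediate early rises lay on the contralateral side, where that list was lower at 6 and 12 h.

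Whether the difference between hemispheres changes with time was tested directly. The ipsilateral to contralateral difference changed between times in 242 genes. The largest effect was at 3 h in 7, at 6 h in 37, all of them risen, at 12 h in 84 and at 24 h in 114, of which 57 had risen and 57 fallen. Egr1, an immediate early transcription factor, followed the 6 h course, with log2 fold changes of 1.46 ± 0.26, 2.4 ± 0.27, 0.67 ± 0.26 and -0.21 ± 0.26 at 3, 6, 12 and 24 h (adjusted p = 0.00482, and 0.0684 with a replicate block within each time). Of the negative regulators of growth factor signalling, Dusp6 had 0.68 ± 0.18, 1.57 ± 0.18, 0.84 ± 0.18 and -0.16 ± 0.17 (adjusted p = 0.00482). Spry4 had 0.44 ± 0.13, 1.35 ± 0.13, 1.31 ± 0.13 and 0.28 ± 0.13 (adjusted p = 0.00253), about the same at 6 and 12 h. Measured from sham, part of these 6 h values lay on the contralateral side, where Egr1, Spry4 and Dusp6 were lower (-1.67, -0.91 and -1). Each of these calls against sham was lost without some single libraries. Hmox1 had log2 fold changes of 1.1 ± 0.31, 2.77 ± 0.31, 4.17 ± 0.34 and 4.01 ± 0.33 (adjusted p = 0.00323). Wisp1, a secreted matrix-associated signalling gene, reached 2.61 ± 0.24 at 12 h from -0.33 ± 0.23 at 3 h (adjusted p = 0.000165). Adcy7, an adenylate cyclase gene, reached 1.66 ± 0.15 from -0.11 ± 0.15 (adjusted p = 8.91e-05). The interferon-induced GTPase gene Gbp3 was largest at 24 h, with -0.11 ± 0.3, 0.9 ± 0.3, 1.5 ± 0.31 and 2.78 ± 0.32 (adjusted p = 0.00482). With replicate number as a block the count was 411. The count was 433, 141 and 152 without contralateral replicate 1 at 3 h, 3 at 6 h and 3 at 12 h, and 124 and 103 without contralateral replicates 1 and 2 at 24 h. It was 146, 135 and 123 without the ipsilateral 3 h replicates in turn. It was 140, 136, 424 and 475 without ipsilateral replicate 1 at 6 h, 1 and 2 at 12 h and 3 at 24 h. Of the 20 genes named by the rule 17, the 7 above included, kept their call without any single library. Without replicate 1, 2 or 3 of every group only 16, 4 and 156 genes passed, 12, 4 and 74 of them among the 242.

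The log2 fold change between hemispheres was higher at 24 h than at 3 h in 291 genes and lower in 309 (901 genes in all with a replicate block). The 23 interferon-stimulated genes shifted by a median of 1.03 (9 passed, 17 adjusted over the list alone; adjusted p = 0.0306 with an estimated correlation), between 5 without contralateral replicate 2 at 24 h and 10 without ipsilateral replicate 3 at 24 h. Of the 16 oxidative stress genes 7 shifted upward (9 adjusted over the list alone; adjusted p = 0.0284 with an estimated correlation), 2 of them without contralateral replicate 2 at 24 h. Of the 18 neuron markers 6 shifted downward (8 adjusted over the list alone; median -0.42; adjusted p = 0.0306 with an estimated correlation), between 2 without contralateral replicate 2 at 24 h and 8 without contralateral replicate 2 at 3 h. Of the 23 immediate early genes 3 shifted downward (6 adjusted over the list alone; median -0.88; adjusted p = 0.315 with an estimated correlation), between 2 without contralateral replicate 1 and 5 without contralateral replicate 3 at 24 h. The total of 600 became 1113 and 926 without contralateral replicates 2 and 3 at 3 h, and 249 and 232 without ipsilateral replicates 2 and 3 at 3 h. It became 253 and 244 without contralateral replicates 1 and 2 at 24 h, and 326 without ipsilateral replicate 1 at 24 h. Without replicate 1, 2 or 3 of every group it was 141, 0 and 149.

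**Figure D2:**
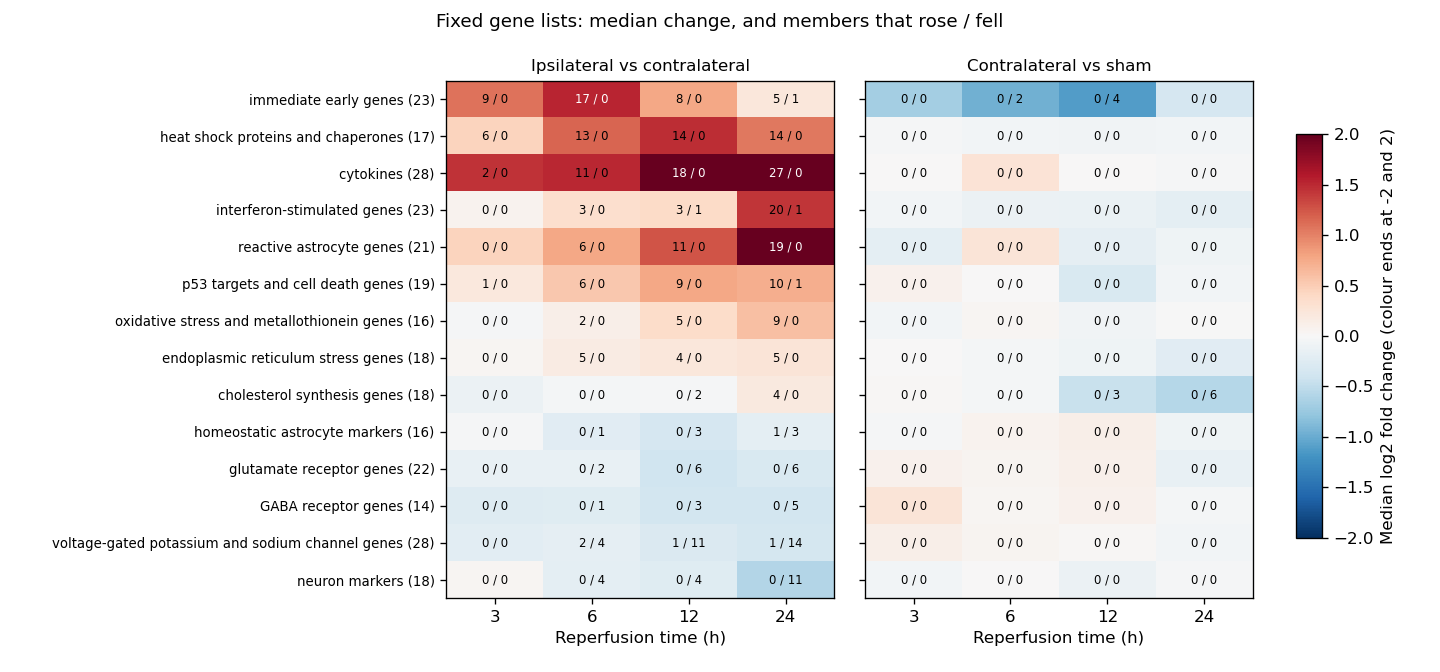
Median log2 fold change of fixed gene lists (rows, with the number of genes tested) by reperfusion time in hours, ipsilateral against contralateral and contralateral against sham; each cell prints how many members rose and fell. Cytokine and reactive astrocyte genes reached 27 of 28 and 19 of 21 rises at 24 h, and 11 of 18 neuron markers fell.

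The title of the series names glutamate homeostasis, so the glutamate genes were followed in every group. Slc1a2, which encodes the main astrocyte glutamate transporter GLT-1 (chromosome 2, 102658659 to 102790784, plus strand), did not differ detectably. Its level was 2970 ± 394 CPM (SD, n = 3) in sham. At 3, 6, 12 and 24 h it was 2970 ± 251, 2780 ± 218, 2500 ± 299 and 2980 ± 497 ipsilaterally and 3620 ± 418, 2940 ± 464, 2990 ± 403 and 2700 ± 337 contralaterally. Its log2 fold changes between hemispheres were -0.29 ± 0.14, -0.08 ± 0.14, -0.26 ± 0.14 and 0.14 ± 0.14 (adjusted p = 0.47, 0.786, 0.247 and 0.514). Against sham the ipsilateral values lay between -0.25 and 0.01 and the contralateral ones between -0.14 and 0.28. Slc1a3, the transporter GLAST, had -0.09, -0.09, -0.32 and 0.08 between hemispheres (lowest adjusted p = 0.155, at 12 h). Glul, which encodes glutamine synthetase, fell 1.39-fold at 12 h (-0.47 ± 0.11, adjusted p = 0.0069; 1030 ± 127 against 1430 ± 93.0 CPM) and 1.31-fold at 24 h (adjusted p = 0.0184). Its adjusted p was 0.0827 at 12 h without ipsilateral replicate 1. At 24 h it was 0.0568 and 0.0503 without contralateral replicates 1 and 3 and 0.0634 and 0.0885 without ipsilateral replicates 2 and 3. Against sham Glul did not pass, with -0.16 ± 0.11 at 12 h and -0.29 ± 0.11 at 24 h (adjusted p = 0.404 and 0.0685).

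Of the 20 glutamate transport and metabolism genes 2 rose and 4 fell at 24 h between hemispheres (2 and 5 adjusted over the list alone; camera adjusted p = 0.0856). The rises were Slc7a11, the cystine-glutamate exchanger (2.84-fold, adjusted p = 0.00097), and the neutral amino acid transporter gene Slc1a4 (1.42-fold), and the falls included Slc17a7 and the transaminase gene Got1 (1.45-fold lower, adjusted p = 0.000565). Of the 22 glutamate receptor genes 6 fell at 12 h and 6 at 24 h and none rose (11 and 7 adjusted over the list alone; adjusted p = 0.176 and 0.278 with an estimated correlation), including the NMDA receptor subunit gene Grin2a (1.43-fold lower at 12 h and 1.45-fold at 24 h) and the metabotropic receptor gene Grm2 (1.57- and 1.47-fold lower). These counts were 10 with a replicate block at 12 h, 2 without ipsilateral replicate 1 at 12 h and 2 without contralateral replicate 2 at 24 h. Of the 14 GABA receptor genes 5 fell at 24 h (9 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation), including Gabbr1 (1.45-fold lower), and 8 with a replicate block.

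Because the series title also names AGO CLIP, which maps the sites where microRNAs bind, predicted microRNA targets were compared between hemispheres. Of 26 literature targets of miR-29, 5 rose at 6 h, 6 at 12 h and 7 at 24 h, when 2 fell (8, 7 and 9 rises adjusted over the list alone; adjusted p = 0.128, 0.167 and 0.0931 with an estimated correlation). The 2 falls were absent without ipsilateral replicate 1. The members that rose were the cell cycle kinase gene Cdk6 (3.62-fold at 6 h, 3.68-fold at 24 h), the survival gene Mcl1 (1.64-fold at 24 h), the basement membrane collagen gene Col4a1 (2.76-fold at 24 h) and others, and the target Slc1a2 was not among them. Genes with a perfect seed site of 1 of 15 microRNA families in the 3' untranslated region, among 15593 tested genes with such a region, were compared with all others. No family passed camera at any time. The 532 genes with a miR-29 site had mean log2 fold changes of 0.04, 0.15, 0.18 and 0.2 at 3, 6, 12 and 24 h against 0.07, 0.09, 0.12 and 0.14 in the others (camera adjusted p = 0.551, 0.0756, 0.589 and 0.736). Against 1000 random gene sets matched for length of that region, their mean was above that of the matched sets at 24 h (permutation adjusted p = 0.045), with adjusted p = 0.423, 0.075 and 0.06 at 3, 6 and 12 h. The 656 genes with a let-7 site and the 785 with a miR-9 site lay higher than matched sets at 6, 12 and 24 h (adjusted p = 0.01, 0.015 and 0.015 for each). Sets for miR-132, miR-30 and miR-26 at 6 h (adjusted p = 0.01, 0.045 and 0.048) and for miR-125 at 24 h (adjusted p = 0.045) differed from matched sets too. With the shorter 7mer sites the let-7 and miR-9 calls ended (adjusted p = 0.661, 0.15 and 0.19 for let-7 and 0.167, 0.12 and 0.066 for miR-9 at 6, 12 and 24 h). The miR-132, miR-30, miR-26 and miR-125 calls ended too (0.11, 0.145, 0.145 and 0.066). The 7mer sets that passed were those of miR-138 at 3 h (adjusted p = 0.03), of miR-29 at 12 h (0.03; 0.21 at 6 h) and of miR-29, miR-124 and miR-128 at 24 h (0.04 each).

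The comparison of ipsilateral cortex with sham asks the same question against animals without a stroke, and the 3 sham libraries serve every time. Hspa1a was 47.6-, 111-, 49.8- and 37-fold higher than in sham at 3, 6, 12 and 24 h (log2 5.57 ± 0.39, 6.8 ± 0.41, 5.64 ± 0.39 and 5.21 ± 0.38; n = 3 per group). Gfap rose 2.91-fold at 12 h (adjusted p = 0.00124) and 5.35-fold at 24 h (adjusted p = 1.24e-05). Fos did not pass at 3 h (2.32-fold, adjusted p = 0.502), 12 h (1.92-fold lower, adjusted p = 0.291) or 24 h (1.11-fold, adjusted p = 0.871). At 6 h Fos rose 3.63-fold (adjusted p = 0.0467). This call ended without sham replicates 1, 2 and 3 (adjusted p = 0.0721, 0.173 and 0.15) and ipsilateral replicates 1 and 2 (0.163 and 0.131). At the 4 times 41, 909, 1191 and 2043 genes rose and 3, 197, 673 and 1965 fell.

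At 24 h against sham 27 of 28 cytokine genes rose (27 adjusted over the list alone; adjusted p = 0.0261 with an estimated correlation). So did 20 of 21 reactive astrocyte genes (21 adjusted over the list alone; adjusted p = 0.0261 with an estimated correlation) and 18 of 23 interferon-stimulated genes, with 1 falling (19 and 1 adjusted over the list alone; adjusted p = 0.0288 with an estimated correlation; 11 rising without sham replicate 2). Of 18 neuron markers 11 fell (11 adjusted over the list alone; adjusted p = 0.0153 with an estimated correlation). Of 28 channel genes 17 fell (19 adjusted over the list alone; adjusted p = 0.0333 with an estimated correlation; 9 without sham replicate 3). Chaperones rose at every time, 6, 13, 15 and 13 of 17 (10, 15, 16 and 13 adjusted over the list alone; highest adjusted p = 0.00949 with an estimated correlation). Immediate early genes were fewer than between hemispheres, with 6 of 23 rising at 6 h (11 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation; 2 without sham replicate 2). At 12 h 2 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.194), with none falling without sham replicate 1. Of 18 cholesterol synthesis genes 11 fell at 12 h (14 adjusted over the list alone; median -0.58; adjusted p = 0.0371 with an estimated correlation), between 6 without ipsilateral replicate 1 and 13 without ipsilateral replicate 3. At 24 h 6 fell (6 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation), between 3 without ipsilateral replicate 3 and 8 without ipsilateral replicate 1.

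The counts against sham were 18, 18 and 11 at 3 h (of 44), 553, 527 and 602 at 6 h (of 1106) and 1048, 1048 and 1028 at 12 h (of 1864) without sham replicates 1, 2 and 3. The count was 2464 at 24 h (of 4008) without sham replicate 1. Without the ipsilateral replicates they were 28, 26 and 20 in turn at 3 h, 639 and 423 without replicates 1 and 2 at 6 h, and 760 and 1087 without replicates 1 and 3 at 12 h.

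The comparison of contralateral cortex with sham asks what a stroke on the other side changes in tissue that was not occluded. Sham animals had surgery too. The time of their collection is not stated, so time after surgery and hour of day could also differ. Few genes passed, and most were lower than in sham. At 3 h Spry4, a feedback inhibitor of growth factor signalling, was 2.09-fold lower (-1.07 ± 0.13, adjusted p = 0.000203, n = 3 per group) and the clock gene Per2 2.21-fold lower (-1.15 ± 0.18, adjusted p = 0.00767). At 6 h 6 genes fell, among them Arc, a synaptic immediate early gene (chromosome 15, 74669083 to 74672570, minus strand; 54.0 ± 12.7 against 233 ± 41.3 CPM, 4.32-fold lower, adjusted p = 0.0414), Egr1 (3.18-fold lower), Spry4 (1.88-fold lower), Dusp6 (2-fold lower) and Rnd3 (2.02-fold lower). At 3 and 6 h no gene rose in the edgeR test. There 1563 and 778 genes had an unadjusted p under 0.05, 904 being the number chance gives. DESeq2 called 34 and 19 genes in either direction. Of the 23 immediate early genes 0 and 2 fell at 3 and 6 h (12 and 17 adjusted over the list alone; medians -0.68 and -0.96; adjusted p = 0.217 and 0.00883 with an estimated correlation). The 2 that fell at 6 h were Arc and Egr1, and none fell without sham replicate 1. The 9 choroid plexus markers at 6 h had a median of 1.67 with no member passing (0 adjusted over the list alone; adjusted p = 0.891 with an estimated correlation).

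Spry4 at 3 h kept its call without any single library, and the other early calls did not. With only the 2 groups compared, and without replicate 3 of every group, Spry4 lost its call at 3 h too. Per2 reached an adjusted p of 0.147 without sham replicate 3 and 0.0796 and 0.0595 without contralateral replicates 1 and 2. The count of 2 at 3 h was 1 without sham replicate 3 or contralateral replicate 1, 4 without contralateral replicate 3, and 6 with a replicate block. The 6 h count was 1, 3 and 0 without sham replicates 1, 2 and 3, and 1, 0 and 1 without contralateral replicates 1, 2 and 3. None of the 5 named genes at 6 h kept its call throughout. In the order of these 6 libraries Arc reached 0.216, 0.102, 0.206, 0.513, 0.193 and 0.324, and Rnd3 0.0991, 0.133, 0.158, 0.163, 0.308 and 0.172. Egr1 reached 0.111 and 0.0812 without sham replicates 1 and 3, and 0.163, 0.147 and 0.158 without the contralateral ones. Dusp6 reached 0.216 and 0.158 without sham replicates 1 and 3, and 0.163, 0.193 and 0.212 without the contralateral ones. Spry4 reached 0.0617 and 0.0619 without sham replicate 3 and contralateral replicate 2.

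At 12 h 17 genes rose and 26 fell in contralateral cortex. Arl4d, a small GTPase gene (2.87-fold lower, -1.52 ± 0.2, adjusted p = 0.000429), and Sik1, a salt-inducible kinase gene (2.6-fold lower, adjusted p = 0.00235), fell without depending on any single library, and Arc (4.94-fold lower), the phosphatase gene Dusp1 (3.19-fold lower) and Junb (3.32-fold lower) fell with them. Glp2r, a gut peptide receptor gene (2.17-fold), and Slco1a4, an organic anion transporter gene of brain endothelium (2.01-fold), rose. Of the 23 immediate early genes 4 fell (18 adjusted over the list alone; median -1.12; adjusted p = 0.00528 with an estimated correlation), and none fell without sham replicate 1. Of the 18 cholesterol synthesis genes 3 fell (13 adjusted over the list alone; median -0.45; adjusted p = 0.00528 with an estimated correlation), led by Mvd, a mevalonate pathway decarboxylase (chromosome 8, 122433601 to 122443422, minus strand; 2.32-fold lower). With a replicate block 5 fell, and 1 fell without sham replicate 1. Of 18 hypoxia-inducible genes 2 fell, the stress gene Ndrg1 (1.53-fold lower) and the glycolysis regulator Pfkfb3 (1.57-fold lower), and 0 without sham replicate 1 (3 adjusted over the list alone; adjusted p = 0.0308 with an estimated correlation). Ndrg1 reached an adjusted p of 0.125, 0.0642 and 0.113 without the sham replicates in turn, and 0.0738 and 0.275 without contralateral replicates 2 and 3. Pfkfb3 reached 0.172, 0.0616 and 0.0962 without the sham replicates in turn, and 0.075 and 0.272 without contralateral replicates 1 and 3.

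At 24 h 5 genes rose and 15 fell. Of the cholesterol synthesis genes 6 of 18 fell (13 adjusted over the list alone; median -0.57; adjusted p = 0.000531 with an estimated correlation), including Mvd (7.29 ± 1.24 against 15.1 ± 0.788 CPM, 2.08-fold lower, adjusted p = 0.011), the sterol demethylase gene Cyp51 (1.63-fold lower) and the farnesyl diphosphate synthase gene Fdps (1.66-fold lower), with none falling without sham replicate 1 and 3 without contralateral replicate 3. Cyp51 reached an adjusted p of 0.0852 and 0.0897 without sham replicates 1 and 3, Fdps 0.1 and 0.0975 without sham replicates 1 and 2, and the pair reached 0.131 each without contralateral replicate 1 and 0.0867 and 0.109 without contralateral replicate 2. Of 12 oligodendrocyte markers, whose cells make much of the brain's sterol, none passed (3 lower adjusted over the list alone; median -0.48; adjusted p = 0.341 with an estimated correlation). Of 8 blood cell markers 2 fell (7 adjusted over the list alone; median -0.94; adjusted p = 0.0179 with an estimated correlation), the globin genes Hbb-bt (2.39-fold lower) and Hba-a2 (2.11-fold lower), whose reads are shared with near-identical globin genes, and none without sham replicate 1. Gpr153, an orphan receptor gene, was 2.29-fold lower (adjusted p = 0.011), and Glp2r and Slco1a4 were 2.38- and 2.06-fold higher. No immediate early gene passed at 24 h (0 adjusted over the list alone; median -0.34; adjusted p = 0.525 with an estimated correlation).

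The 12 h count of 43 was 8, 21 and 21 without sham replicates 1, 2 and 3 and 22 and 14 without contralateral replicates 2 and 3. Arc and Dusp1 at 12 h reached an adjusted p of 0.0555 and 0.0592 without sham replicate 1, and 0.0735 and 0.0688 without contralateral replicate 3. Junb reached 0.253, 0.0642 and 0.055 without the sham and 0.0879, 0.124 and 0.271 without the contralateral replicates in turn. Glp2r reached 0.159, 0.154 and 0.346 without sham replicates 1 and 2 and contralateral replicate 3. Slco1a4 reached 0.159, 0.101 and 0.0879 without sham replicates 1 and 2 and contralateral replicate 1.

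The 24 h count of 20 was 3, 5 and 6 without sham replicates 1, 2 and 3 and 1 and 1 without contralateral replicates 1 and 2, and none of the 8 named genes kept its call throughout. Mvd reached an adjusted p of 0.0852 and 0.0526 without sham replicates 1 and 3, and 0.131 and 0.068 without contralateral replicates 1 and 2. Gpr153 reached 0.0526 without sham replicate 3, and 0.0679 and 0.0742 without contralateral replicates 1 and 2. Glp2r reached 0.118 and 0.161 without sham replicates 1 and 2, and 0.123 and 0.068 without contralateral replicates 1 and 2. Slco1a4 reached 0.182, 0.198, 0.131 and 0.0742 without the same 4 libraries. Hba-a2 reached 0.252, 0.0966 and 0.214 without the sham replicates in turn, and 0.238 and 0.232 without contralateral replicates 1 and 2. Hbb-bt reached 0.27, 0.0582 and 0.217 without the sham and 0.143, 0.182 and 0.166 without the contralateral replicates in turn.

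**Figure D3:**
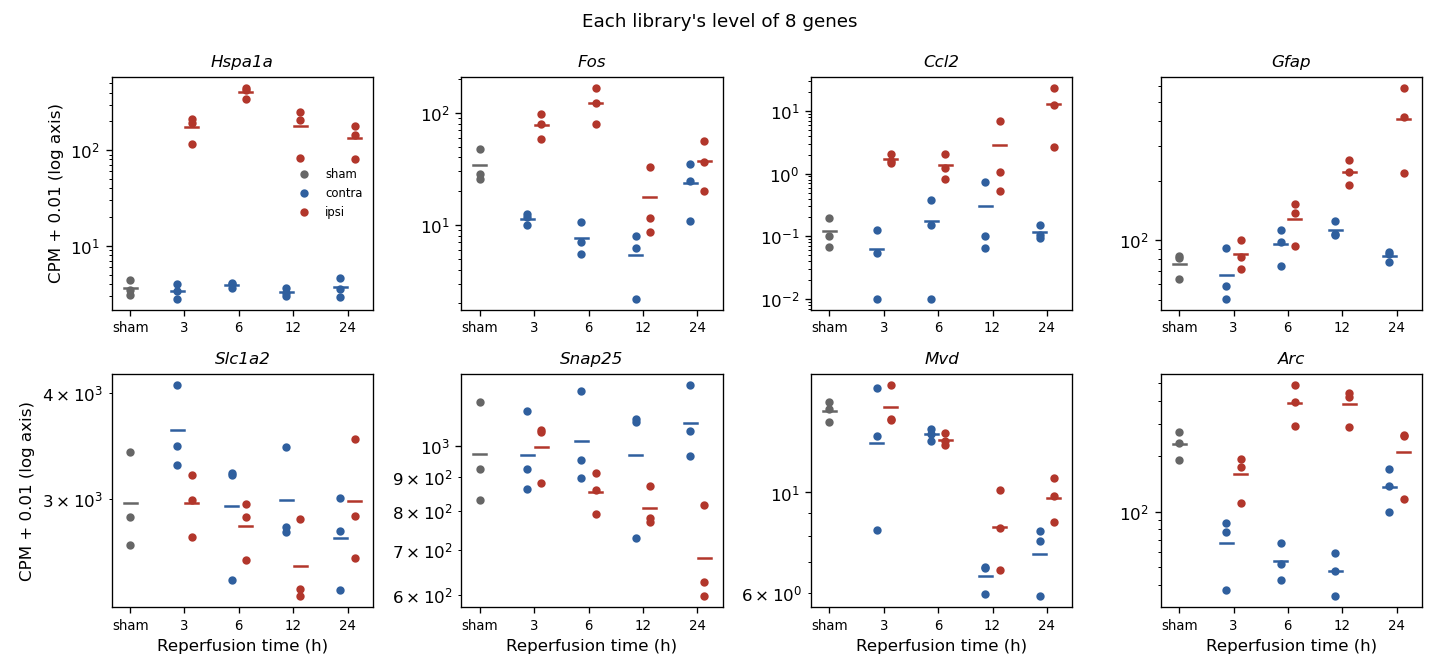
CPM on a log axis for each library (points) and group means (bars), by reperfusion time in hours, in sham, contralateral and ipsilateral cortex. Hspa1a averaged 3.63 in sham and 404 in ipsilateral cortex at 6 h, while Slc1a2 averaged 2970 in sham and between 2500 and 2980 ipsilaterally.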

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

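Genes whose ipsilateral to contralateral effect changed with time were set apart by a rule fixed in advance. There were 242 in the test over the 4 times and 600 in the test of 24 h against 3 h. The 20 named ones follow with their adjusted p in the 4-time test.

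With their largest effect at 3 h were Ankrd34c, an ankyrin repeat gene (0.86, 0.41, -0.81 and -0.63 at 3, 6, 12 and 24 h; adjusted p = 0.00253), Hunk, a neural kinase gene (0.52, 0.33, -0.43 and -0.42; 0.0127), Ccdc47, of the endoplasmic reticulum (-0.37, -0.35, 0.21 and 0.25; 0.0232), Nptx1, a neuronal pentraxin gene (-0.59, -0.32, 0.4 and -0.22; 0.0318), and Osbpl3, an oxysterol-binding gene (0.54, 0.1, -0.31 and -0.5; 0.0384). The last 3 lost their call without 3, 10 and 10 of 24 single libraries, with adjusted p up to 0.0615 for Ccdc47 without contralateral replicate 2 at 24 h, 0.0946 for Nptx1 without ipsilateral replicate 1 at 12 h and 0.102 for Osbpl3 without ipsilateral replicate 3 at 3 h. Ankrd34c was higher in contralateral cortex than in sham at 12 h (0.98 ± 0.19, edgeR adjusted p = 0.0144), a call that depended on single libraries. Its -0.81 at 12 h need therefore not be an ipsilateral fall.

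With their largest effect at 6 h were the signalling inhibitor Spry4 (1.35, and 1.31 at 12 h; adjusted p = 0.00253) and the Ras-like gene Rasl11b, the phosphatase gene Dusp6, the transcription factor Mycn and Egr1 (0.00482 each). Mycn, for example, had 1.2, 1.7, 0.67 and -0.47.

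With their largest effect at 12 h were Adcy7 (8.91e-05), Wisp1 (0.000165), the transcriptional corepressor Cbfa2t3 (0.00253), Hmox1 (0.00323) and Loxhd1, a hair cell gene (0.00508), which had -0.74, 1.6, 4.21 and 3.35. With their largest effect at 24 h were the folate enzyme gene Aldh1l2 (0.00253) and Cyb5r1, Gbp3, Gbp7 and Txnrd1 (0.00482 each), the last 3 being 2 interferon-induced GTPases and thioredoxin reductase. Gbp7 had -0.58, 0.97, 0.42 and 1.83. Aldh1l2 had 1.31 ± 0.18 at both 12 and 24 h, and Txnrd1 had 1.19 ± 0.12 and 1.24 ± 0.12, about the same. The time of largest effect was read from the estimates and was not tested against neighbouring times.

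For 3 patterns other explanations were weighed, of which the tests of depth, of spread at 3 h and of ipsilateral replicate 1 at 24 h were set before their values were seen and the others, with the splits of libraries, after.

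Few genes differed between hemispheres at 3 h, 45 against 1445 at 6 h. With the GC correction the counts were 60 and 2041, so the GC trend of contralateral replicate 1 did not account for the gap. With every library thinned to the smallest total 1328 genes still passed at 6 h and 40 at 3 h, which excluded sequencing depth. Genes that rose at 6 h had a median log2 fold change of 0.26 at 3 h against 0.63 at 12 h, a ratio of 0.417, so their effect itself was smaller at 3 h and a larger spread alone did not account for it.

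Cholesterol synthesis genes were lower in contralateral cortex than in sham at 12 and 24 h. Against contralateral cortex at 3 h, with no sham library, the list at 24 h had a median of -0.66 (camera adjusted p = 4.9e-17, adjusted p = 0.0229 with an estimated correlation, 7 genes lower). At 24 h the 3 sham libraries alone were therefore not the cause, and no such comparison was made for 12 h. The list fell by more than the oligodendrocyte markers did in the 6 late libraries against the 9 others (difference -0.24, one-sided exact permutation p = 0.0102). The late libraries were chosen after the list was seen to be low in them, and the 9 others included sham. The permutation also did not keep the surgery day, so fewer oligodendrocytes were not excluded. Time of day at collection may have contributed: 4 clock genes passed adjusted over the list alone at 12 and 24 h together, which lies between the bounds set after that value was seen, and the time of sham collection is not stated.

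Neuron markers were lower in ipsilateral cortex at 24 h, with a median of -0.58. The 18 values ran from -0.87 to 0.25 with an SD of 2.31 times their median SE, more than an equal fall of all 18 would give. Loss of some kinds of neuron more than others would also spread the values. A smaller share of neurons was therefore not excluded. With the GC correction 11 markers fell, the same number as without, so GC trends were not the cause. Without ipsilateral replicate 1, the library with the highest mitochondrial ribosomal RNA share, the median was -0.55.

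Group labels were also reassigned among the libraries of each comparison. For the 12 comparisons of 3 against 3 libraries and for 24 h minus 3 h, 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes. The real counts and the highest other counts were 45 and 0, 1445 and 0, 2214 and 0, and 3455 and 53 between hemispheres at 3, 6, 12 and 24 h, 44 and 0, 1106 and 1, 1864 and 0, and 4008 and 0 for ipsilateral cortex against sham, 2 and 1, 6 and 0, 43 and 0, and 20 and 0 for contralateral cortex against sham, and 600 and 1 for 24 h minus 3 h. Among 100 splits only the real one reached 5967 genes for the mean of the 4 times, the highest other giving 818, and only the real one reached 242 for the test of differing effects, the highest other giving 16, a share of 0.01 in both. Splits that keep the surgery day were then run. With hemispheres swapped only within a time and replicate number, 1 of 100 splits, the real one, reached 5967, the highest other giving 4083, a share of 0.01. With times exchanged only within a replicate number, 2 of all 576 splits reached 242, a share of 0.00347. The other split, which exchanged replicate 3 between 12 and 24 h, gave 270.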

How the results depend on the processing

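Signs were followed only for the named genes and list members. None of those that passed the test changed its sign under an alternative, while Slc1a2 at 6 h, which did not pass, turned from -0.08 to 0.05 without replicate 3 of every group. Total counts of genes that moved by more than 1.5 times are given below against their reported value, and the cause was not tested.

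Between hemispheres at 3 h 45 genes passed, against 77 with the GC correction and replicate block, 18 with only the 2 groups compared, 133 with DESeq2 and 29 with the 2 libraries that stand apart left out. At 6 h the 1445 genes became 2241 with the GC correction and replicate block, 2445 with only the 2 groups and 2455 without the 2 libraries. At 12 h the 2214 became 3468 without the 2 libraries. At 24 h no change of method moved the 3455.

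For ipsilateral cortex against sham the 44 genes at 3 h became 92 with the GC correction, 119 with it and a replicate block, 240 with only the 2 groups, 173 with DESeq2 and 139 without the 2 libraries. The 1106 at 6 h became 1798 with the GC correction and block, 2117 with only the 2 groups and 1944 without the 2 libraries, and the 1864 at 12 h became 2824, 3034 and 3121 with the same 3 changes.

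For contralateral cortex against sham the 2 genes at 3 h became 4 with DESeq2 size factors, 6 with no low-count filter, 5 with the stricter filter, 5 with abundant RNAs left out, 6 with the replicate block, 6 with the GC correction, 13 with GC correction and block, 1 with only the 2 groups, 34 with DESeq2 and 1 without the 2 libraries. The 6 at 6 h became 27 with only the 2 groups and 19 with DESeq2. The 43 at 12 h became 72 with the GC correction, 86 with it and the block, 238 with only the 2 groups, 141 with DESeq2 and 151 without the 2 libraries. The 20 at 24 h became 34, 45, 83, 66 and 60 with the same 5 changes.

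The test that effects differ between times gave 242 genes, against 411 with the replicate block, 384 with a block within each time, 661 with the GC correction, 879 with it and the block, 777 with the DESeq2 likelihood ratio test and 526 without the 2 libraries. The 600 genes of 24 h minus 3 h became 901 with the block, 1120 with the GC correction, 1346 with both and 1208 with DESeq2.

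With 1 library, or 1 replicate number, left out the counts ran from 12 to 132, 155 to 1643, 773 to 2406 and 854 to 2995 between hemispheres at 3, 6, 12 and 24 h, from 9 to 50, 132 to 1216, 450 to 1960 and 1178 to 3394 for ipsilateral cortex against sham, and from 0 to 4, 0 to 3, 6 to 45 and 0 to 19 for contralateral cortex against sham. They ran from 3024 to 6845 for the mean of the 4 times, 4 to 475 for differing effects and 0 to 1113 for 24 h minus 3 h. Of the lowest values, 773 came without replicate 3 of every group, and 12, 155, 854, 3024, 4 and this 0 came without replicate 2. The log2 fold change of Slc1a2 between hemispheres ran from -0.34 to -0.18, -0.23 to 0.05, -0.42 to -0.08 and 0 to 0.25 at 3, 6, 12 and 24 h.

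Of the 33 lists 12, 17, 15 and 18 passed camera between hemispheres at 3, 6, 12 and 24 h, and 3, 3, 3 and 8 with an estimated correlation; the rotation test fry gave 5 at 3 h. For contralateral cortex against sham 4, 5, 10 and 15 lists passed, 0, 1, 3 and 3 with an estimated correlation and 0, 1, 4 and 3 with fry, and 3 at 6 h with the GC correction.

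The replicate block changed the call of 9 lists. Microglia markers at 3 h between hemispheres went from 0.0603 to 0.0424, oligodendrocyte precursor markers at 12 h from 0.0452 to 0.0502 and at 24 h from 0.0422 to 0.0508, and homeostatic astrocyte markers at 24 h from 0.0485 to 0.0508. Striatal neuron markers went from 0.0837 to 0.0377 in contralateral cortex against sham at 12 h and from 0.0568 to 0.0314 for 24 h minus 3 h. Against sham in ipsilateral cortex, hypoxia-inducible genes at 6 h went from 0.0502 to 0.0413, endothelial markers at 24 h from 0.0272 to 0.0544 and glutamate transport genes at 24 h from 0.044 to 0.052. Among the genes followed in every comparison it changed the call of Fos at 12 h between hemispheres, from 0.0562 to 0.0378. Between hemispheres it moved the glutamate receptor falls at 12 h from 6 to 10, the GABA receptor falls at 24 h from 5 to 8, the immediate early fall at 24 h from 1 to 0 and the fibroblast rises at 24 h from 0 to 2. In contralateral cortex against sham it moved the cholesterol synthesis falls at 12 h from 3 to 5.

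A block within each time changed those of Npas4, Fos, Lrrc57, Gfap and Egr1 given with these genes. At 3 h it moved the immediate early rises from 9 to 5 and the cytokine rises from 2 to 4, and at 12 h the glutamate receptor falls from 6 to 12 and the channel rises from 1 to 2. At 24 h it moved the immediate early fall from 1 to 0, the GABA receptor falls from 5 to 9, the channel rises from 1 to 2, the endothelial rises from 5 to 3, the oligodendrocyte rises from 2 to 1, the mural rise from 1 to 0 and the fibroblast counts from 0 and 0 to 2 rises and 1 fall. For 24 h minus 3 h it moved the immediate early falls from 3 to 1. At 6 h it added 1 fall to the clock genes and 1 to the activity-regulated genes, which had 0.

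List counts were followed with the GC correction and without the 2 libraries only between hemispheres and in contralateral cortex against sham. With the GC correction the oxidative stress rises at 12 h went from 5 to 8, the glutamate receptor falls at 12 h from 6 to 10, the channel rise at 12 h from 1 to 0, and at 24 h the GABA receptor falls from 5 to 9, the cholesterol synthesis rises from 4 to 7 and the fibroblast rises from 0 to 1. The clock gene falls at 6 h went from 0 to 2, and the cholesterol synthesis falls against sham at 12 h from 3 to 5. Without the 2 libraries the immediate early rises at 3 h went from 9 to 1 and the cytokine rises from 2 to 1, at 6 h the p53 target rises from 6 to 10, the miR-29 target rises from 5 to 8 and the clock gene falls from 0 to 1, and at 12 h the oxidative stress rises from 5 to 8, the glutamate receptor falls from 6 to 10 and the channel rises from 1 to 2. At 24 h the falls went from 3 to 8 for homeostatic astrocyte markers, 4 to 7 for glutamate transport genes, 6 to 10 for glutamate receptors, 5 to 8 for GABA receptors, 1 to 0 for immediate early genes and for p53 targets, and 2 to 0 for miR-29 targets. The rises went from 7 to 1 for neutrophil and monocyte markers, 5 to 1 for endothelial, 5 to 2 for microglia, 5 to 3 for immediate early, 4 to 2 for cholesterol synthesis, 2 to 0 for oligodendrocyte and 1 to 0 for mural genes. Against sham the falls went from 2 to 1 and 4 to 7 for immediate early genes at 6 and 12 h, and from 3 to 7 and 6 to 10 for cholesterol synthesis genes at 12 and 24 h.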

Other observations

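Between hemispheres at 24 h 4 of 18 cholesterol synthesis genes rose (6 adjusted over the list alone; median 0.2; camera adjusted p = 0.0367, adjusted p = 0.472 with an estimated correlation), including Cyp51 (1.52-fold), with 1 rising without ipsilateral replicate 1. Against sham the medians at 24 h were -0.57 contralaterally and -0.3 ipsilaterally, where 6 of 18 fell (6 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation).

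Arc likewise differed from sham on the contralateral side. Its mean was 233 CPM in sham, 67.0, 54.0, 47.2 and 136 contralaterally and 160, 392, 385 and 212 ipsilaterally at 3, 6, 12 and 24 h, so part of its difference between hemispheres at 12 h (8.16-fold) came from the lower contralateral level. This gene was chosen after its values were seen.

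Whether both hemispheres of an animal were sampled could not be read from the labels, and the correlation of 0.317 between same-numbered libraries at 3 h and 0.0207 at 12 h leaves it open. A record of which animal each library came from, and of the hour at which the sham cortex was taken, would settle the pairing and the time-of-day question. Spatial or single-nucleus data from the same times would separate lower expression per neuron from fewer neurons.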
